A study of Mus musculus with 80 samples.

How the data were processed

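The values came from the processed files that the submitters deposited, and no sequencing reads were reprocessed. Per the submitters' processing notes, base calls were made with CASAVA 1.8.4, reads were aligned with Bowtie, Hi-C data were handled with HOMER, enriched islands were called with SICER, and the genome build was mm9. The versions of Bowtie, HOMER and SICER were not given in the sources used here.

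For RNA-seq, the deposited files listed a raw read count and an RPKM (reads scaled by transcript length and library total) for each of 29257 RefSeq transcripts. That the columns hold a count and an RPKM was read from the deposited values, since the whole numbers divided by transcript length were proportional to the RPKM in every file. After 493 transcripts placed at more than 1 locus were left out, each gene was represented by its transcript with the largest total count, and 22543 genes remained. Isoforms of a gene share reads, so the count of a gene is that of a single transcript. For Hi-C, each deposited file held a PC1 score per 20 kb bin and library, the first principal component of the contact correlation matrix made with HOMER per the submitters' processing notes. Positive PC1 marks the active A compartment and negative PC1 the B compartment by the usual convention, and the sign can be set separately for every chromosome. Of 126496 bins, the 125426 with a value in all Hi-C libraries were used. For DNase-seq and BCL11B ChIP-seq, the deposited files held islands with a SICER score per library, per the submitters' processing notes, and this score is not normalized for depth. For MNase-seq, the deposited file names say that nucleosome positions come from DANPOS, with an occupancy signal after smoothing and quantile normalization and a fuzziness score. The contact matrices listed a normalized contact for pairs of 20 kb bins up to 2 Mb apart. Their deposited file names say "norm" for HSC and DN2 and ICE for the cultured cells, so values from these sets were compared only within a set. Lists of interacting regions, pooled over the libraries of a stage and subsampled according to the deposited file names, carried a whole number per pair whose unit was not given in the sources used here. A library number in the name of the CLP list differs from that of CLP replicate 3, so whether that list holds this library is unclear. Positions are in mm9 and counted from 1.

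The groups, the comparisons, the tests, the gene lists and most alternatives were fixed before the data were examined. The plan named limma on log2 RPKM for the Bcl11b knockouts. Because the files held counts, the test was instead edgeR's quasi-likelihood test with TMM normalization and Benjamini-Hochberg adjustment, and limma on log2(RPKM + 1) became an alternative. The 10940 genes with an RPKM of at least 1 in at least 2 of the 8 knockout and control libraries were tested in a single fit of 4 groups, with an adjusted p of 0.05 as threshold, and the interaction contrast was the knockout effect in naive CD4 T cells minus that in DP thymocytes. PC1 was compared with limma in 1 fit over the 30 stage libraries and another over the 4 naive libraries, with Benjamini-Hochberg adjustment over bins. A bin counted as switched when it passed and the group means had opposite signs, and neighbouring switched bins were joined into runs. Counts of changed bins used PC1 as deposited. Named bins, runs and the root mean square change used the values with the sign of chromosomes 2 and X turned in DN2 replicate 2. Islands of all libraries were merged into regions with bedtools, and a region was present in a library when an island overlapped it by at least 1 base. Early stages are HSC to DN2 and late stages DN3 to DP. Expression across the 8 stages had 1 library per stage, and no test per gene was run. A gene was called separated when its 3 late values all lay on the same side of its 5 early values, with no minimum difference. Where a 2-fold difference is named, it is that of the group means of RPKM + 1 on the log2 scale.

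The 19 gene lists were stem and progenitor factors and receptors, myeloid, B lineage, erythroid and megakaryocyte, T lineage identity and pre-TCR signalling, Notch pathway, NK and innate lymphoid, naive and recirculation, activated and memory T, regulatory T, CD8 lineage, helper cytokine and master regulators, positive selection and TCR response, cell cycle, genome architecture, thymic stroma and epithelium, handling stress and immediate early, interferon response, and gamma delta and innate-like T. Lists were tested with camera at a preset correlation of 0.01 between genes, and again with a correlation estimated from the residuals. Adjusted p-values of lists cover the 38 tests of the 19 lists in the 2 cell types. The percentile of a list across stages compares its median with 10000 random lists of the same size. 1 gene of the lists stayed in every test and count, and its own values are not reported here.

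The genes named are Bcl11b, the 10 rising and 10 falling genes with the largest absolute log2 change per cell type among those past the threshold, with knockout values all on the same side of the control values and a mean RPKM of at least 1 in either group, and up to 4 members of every list by size of change. Predicted gene models were skipped. For the interaction they are the 5 genes of each sign with the smallest adjusted p, and across stages the 10 separated genes of each direction with the largest difference plus up to 4 members per list. Naming genes by their position in PC1 bins, accessible regions or contact maps was planned but not done, because no mm9 gene positions were used here. Regions are therefore named by coordinates: the 5 bins and the 5 longest runs of each sign, and the 5 regions of each kind with the highest mean score percentile. That order was chosen after the files were seen.

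Fold changes against a group with 0 reads are lower bounds computed from a floor of 3 counts over the group. With 1 to 3 reads the ratio is given with its 95% counting interval. These floors and intervals cover counting error only, because reads without molecular identifiers are not independent molecules. The naive DNase-seq libraries carry numbers of 2 series, each with both genotypes: replicate 1 of each in the first, and replicates 2 and 3 of each in the second. The labels do not say that replicates were separate animals, so p-values measure the spread between these libraries, which may be technical.

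The knockout RNA test, the PC1 test from DN2 to DN3 and the DNase presence calls were tried on data with planted changes, and the list, exact and permutation tests were not. With 2 libraries per group of naive CD4 T cells, 73% of genes changed 2-fold and 100% of those changed 4-fold were recovered, with 5 false calls among 178. For DP thymocytes the shares were 71% and 98%, with 12 false calls among 181. For PC1 from DN2 to DN3, 54% of bins changed by 20 and 88% of bins changed by 60 were recovered, with 3 false calls among 145. For DNase regions, 60 of 60 late-only, 40 of 40 early-only and 500 of 500 shared regions were recovered.

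Alternatives covered the pseudocount, the low-value filter, quantile normalization, DESeq2's size factors and Wald test, replicate blocks, library series as a batch term, autosomes alone, larger bins, a minimum change, the island score and overlap that count, matched background regions, distance corrections of contact maps, and leaving out every replicated library in turn. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, bedtools 2.31.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.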

Results

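The series followed mouse blood cells from hematopoietic stem cells (HSC) to double positive (DP) thymocytes, which carry both CD4 and CD8, and tested the loss of Bcl11b, a zinc finger transcription factor needed for T-cell commitment. The stages between were multipotent progenitors (MPP), common lymphoid progenitors (CLP), early T-cell progenitors (ETP) and the double negative thymocyte stages DN2, DN3 and DN4. Of 80 samples, 36 were Hi-C, 22 DNase-seq from small numbers of cells, 2 MNase-seq, 16 RNA-seq and 4 BCL11B ChIP-seq. Hi-C of the stages held 30 libraries: 3 of HSC, 2 of MPP, 3 of CLP, 4 of ETP, 3 of DN2, 6 of DN3, 4 of DN4 and 5 of DP. Of these, 1 library each of HSC, MPP and CLP is labelled thymus and the others of these stages bone marrow. Another 2 Hi-C libraries came from DN2 and DN3 cells cultured from bone marrow, and naive CD4 T cells of lymph nodes gave 2 control and 2 Bcl11b knockout libraries. DNase-seq had 2 libraries per stage, made at DNase dilutions of 1:30 and 1:20, and 3 control and 3 knockout libraries of naive CD4 T cells. RNA-seq had 1 library per stage and 2 control and 2 knockout libraries each of DP thymocytes and naive CD4 T cells. The DP knockout libraries were assigned by title, because their strain label does not say BCL11B deficient. Both naive BCL11B ChIP-seq libraries were used, and those of DP thymocytes were not analysed here. Gene counts per RNA-seq library ran from 6689303 in DN2 to 10688004 in naive control replicate 1, while the read depth of the other assays was unknown.

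The stage libraries addressed how expression changes on the way to the T lineage. The CD3 genes Cd3d, Cd3e and Cd3g were lower in every stage up to DN2 than in DN3, DN4 and DP. Cd3e, a subunit of the CD3 signalling complex, stood at an RPKM of 10.5 in HSC, 1.43 in MPP, 0.879 in CLP, 2.54 in ETP and 10.8 in DN2. It then stood at 501 in DN3, 313.5 in DN4 and 443 in DP. Cd3g was at 47.1 in DN2 and 1369 in DN3, and Ptcra, the invariant chain of the pre-T-cell receptor, went from 0.413 in DN2 to 288 in DN3. Bcl11b itself was at 0.230 in ETP, 22.2 in DN2, 57.5 in DN3, 33.1 in DN4 and 65.2 in DP. In HSC it was at 1.29, in MPP at 0.119 and in CLP at 0.0613. Tcf7, a T-lineage factor induced by Notch, was already at 152 in ETP and 462 in DN2. Progenitor genes went the other way, with the stem cell marker Cd34 at 62.9 in DN2 and 0.720 in DN3, and Sfpi1, which encodes the myeloid factor PU.1, at 87.9 in DN2 and 3.41 in DN3. Mpo, the neutrophil granule enzyme, was at 738 in HSC, 103 in DN2 and 0.640 in DN3. Lmo2, a stem cell factor, was lost earlier, with 489.5 in MPP, 48.8 in CLP and 1.65 in DN2.

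With 1 library per stage, differences between single stages could not be tested, and no test per gene was run between early and late stages. Across 12564 genes, 2636 (20.98%) had all values of DN3 to DP on the same side of those of HSC to DN2. Of these, 71 were at least 2-fold higher late and 257 at least 2-fold lower. Chance would give 3.57% if the stages were exchangeable. They follow an order, and neighbours were more alike (r = 0.961 across genes for DN3 and DN4, 0.732 for HSC and DP). The excess over 3.57% is therefore no test of this grouping. Counts of separated genes per list carry no 2-fold requirement, and the share among all genes, both directions together, is 20.98%. The largest late excesses of log2(RPKM + 1) belonged to Sh2d1a (6.72), Cd3d (6.67), Cd3e (6.47), Cd3g (6.26), Ptcra (5.81), Slc16a5 (5.51), Cd8b1 (5.40), Themis (5.38), Lef1 (5.38) and Gzma (5.23). The largest deficits belonged to Mpo (-7.40), Cd34 (-7.05), Ifitm1 (-6.77), Tyrobp (-6.33), Lyl1 (-6.28), Sfpi1 (-6.16), Napsa (-6.12), Hhex (-5.97), Gpr97 (-5.92) and Lmo2 (-5.53). Of 30 T lineage identity genes, 19 were separated and higher late, with a median of 3.86, at percentile 100 of 10000 random lists. Of 22 stem and progenitor genes 14 were separated and lower (median -3.82), and of 20 myeloid genes 12 were (median -2.72), both at percentile 0. Of 13 erythroid and megakaryocyte genes 4 were lower (-1.80), and Hbb-b2, a beta globin, was at 169.6 in DN2 and 0.281 in DN3. Of 15 B-lineage genes 1 was lower (-0.90, percentile 0.15), and Cd79a, a subunit of the B-cell receptor, was at 139.9 in CLP alone and at most 3.90 elsewhere. Of 16 interferon response genes 5 were lower (-0.99, percentile 0). Of 23 NK and innate lymphoid genes 1, Gzma, was higher and 6 were lower (-0.42, percentile 12.1). The positive selection list had 5 of 20 genes higher (1.53, percentile 100), among them Id3 and Ccr9, and the chemokine receptor Ccr9 was at 0.941 in DN2 and 413 in DP.

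Of the other lists, regulatory T genes had 2 of 11 higher and 2 lower (median 0.93, percentile 100), naive and recirculation genes 4 of 14 higher and 1 lower (-0.02, percentile 83.4), and activated and memory T genes 3 of 20 higher and 2 lower (-0.17, percentile 66.7). CD8 lineage genes had 1 of 10 higher and 2 lower (-0.65, percentile 2.46), with Cd8b1 at 3.75 in DN3, 131 in DN4 and 1787 in DP. Helper regulators had 1 of 7 higher (0.74, percentile 99.9). Notch pathway genes had 1 of 10 higher (0.04, percentile 88.9), and the Notch targets Dtx1 and Notch3 peaked in DN3 at 39.3 and 17.9. Genome architecture genes had 2 of 21 higher (0.13, percentile 99.7) and cell cycle genes 0 of 22 (0.08, percentile 98.2). Thymic stroma genes had 1 of 6 lower (-0.64, percentile 3.64), stress genes 1 of 14 lower (-0.15, percentile 54.9) and gamma delta genes 1 of 7 higher (0.14, percentile 93.3).

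Hi-C of the stages asked when chromosome compartments change. The longest switch between early and late stages lay on chromosome 12 from 107380001 to 109200000 (mm9), the chromosome that carries Bcl11b. PC1 there averaged -43.8 over HSC to DN2 and 67.7 over DN3 to DP, across 91 bins. In its strongest bin, 108040001 to 108060000, PC1 was -77.3 ± 3.8 in HSC (SD, n = 3), -73.1 ± 2.2 in MPP (n = 2), -74.4 ± 6.2 in CLP (n = 3) and -77.2 ± 1.8 in ETP (n = 4). It was -26.8 ± 5.6 in DN2 (n = 3), 70.4 ± 3.0 in DN3 (n = 6), 66.0 ± 3.7 in DN4 (n = 4) and 72.0 ± 3.0 in DP (n = 5). The late minus early change of this bin was 135.23 (limma, adjusted p = 2.7e-30). The distal part of the interval, from 108240001 to 109220000, switched first, from -58.4 in ETP to 16.4 in DN2. The part from 107420001 to 108240000 followed, from -19.5 in DN2 to 67.2 in DN3. Whether the interval includes Bcl11b was not determined, because no mm9 gene positions were used here.

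**Figure D1:**
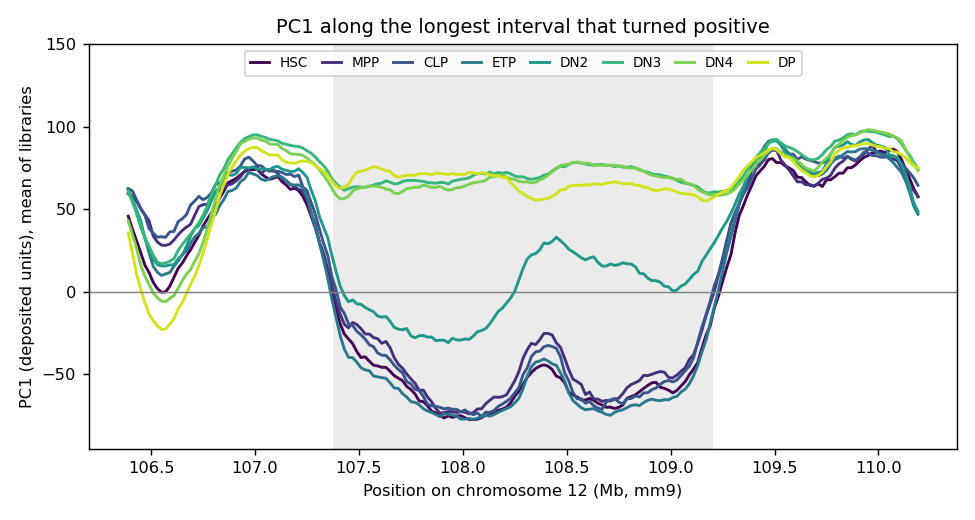
Mean PC1 per stage (y axis, the score of HOMER) in 20 kb bins along chromosome 12 (x axis, mm9) around 107380001 to 109200000, a line per stage. PC1 of the bin from 108040001 to 108060000 rises from -77.2 in ETP over -26.8 in DN2 to 70.4 in DN3.

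Other intervals that turned from negative to positive PC1 between the early and late stages lay on chromosome 13 from 9240001 to 10180000 (-16.2 to 28.7) and chromosome 15 from 93400001 to 94320000 (-28.2 to 30.9). On chromosome 2, 50460001 to 51720000 turned from 49.2 to -27.9, and on chromosome 17, 43160001 to 44140000 turned from 22.0 to -14.6. The bin with the largest loss, 111500001 to 111520000 of chromosome 13, went from 71.7 to -29.5 (change -101.17, adjusted p = 8.9e-23). In total PC1 changed in 75835 of 125426 bins between early and late stages, rising in 37444 and falling in 38391. Of these, 4685 turned positive and 3818 turned negative. With library series as a batch term, 76734 bins changed.

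Steps between neighbouring stages differed in size. From HSC to MPP PC1 changed in 7689 bins (4826 up, 2863 down), and chromosome 12 from 114780001 to 116300000 turned from -35.7 to 31.5. From MPP to CLP it changed in 7080 bins (2189 up, 4891 down), and chromosome 14 from 23020001 to 23720000 turned from 39.3 to -24.1. CLP to ETP changed 24471 bins (11396 up, 13075 down; 22154 without the CLP library labelled thymus), with chromosome 2 from 9060001 to 9720000 turning from -28.1 to 37.0 and chromosome 4 from 86920001 to 87560000 from 48.2 to -16.6. ETP to DN2 changed 3693 bins (1339 up, 2354 down), fewer than any other step. DN2 to DN3, when cells commit, changed 42481 bins (21767 up, 20714 down), and DN3 to DN4 19512 (10089 up, 9423 down), with chromosome 5 from 119360001 to 120020000 turning from 18.5 to -23.2. DN4 to DP changed 53894 bins (21967 up, 31927 down), with chromosome 14 from 15940001 to 16520000 turning from -19.3 to 49.6. The root mean square change of PC1 was 8.67, 8.12, 12.0, 5.79, 13.2, 8.95 and 12.3 for the 7 steps in order. It was corrected for the spread between replicates, with the signs of DN2 replicate 2 turned. By this measure the step from DN2 to DN3 moved PC1 most. After quantile normalization, leaving out single libraries gave 12.5 to 13.3 for DN2 to DN3 and 11.8 to 12.8 for CLP to ETP. These ranges overlap.

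Counts of bins depended on the smallest change that counts, on scale and on single libraries. Among bins that changed by at least 0.5 SD of PC1, 1945 rose and 35 fell from DN4 to DP, and 116 rose and 691 fell from DN3 to DN4, so the balance of both steps changed. Quantile normalization moved DN4 to DP to 29760 bins (14845 up, 14915 down), HSC to MPP to 11708 (6241 up, 5467 down), MPP to CLP to 10194 (4550 up, 5644 down) and ETP to DN2 to 3836 (2125 up, 1711 down). In DN2 replicate 2 PC1 ran opposite to the other libraries on chromosomes 2 (r = -0.989) and X (r = -0.986, across bins), and with both turned 35661 bins changed from DN2 to DN3 and 81572 between early and late. Without that library 27037 changed from DN2 to DN3. ETP to DN2 changed 17144 bins without DN2 replicate 1 and 20277 without DN2 replicate 3, where replicate 2, with its opposite chromosomes, was 1 of the 2 DN2 libraries left. It changed 1846 without ETP replicate 2 and 1945 without ETP replicate 3, and MPP to CLP changed 2138 without MPP replicate 1. With library series as a batch term ETP to DN2 changed 5583 bins.

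**Figure D2:**
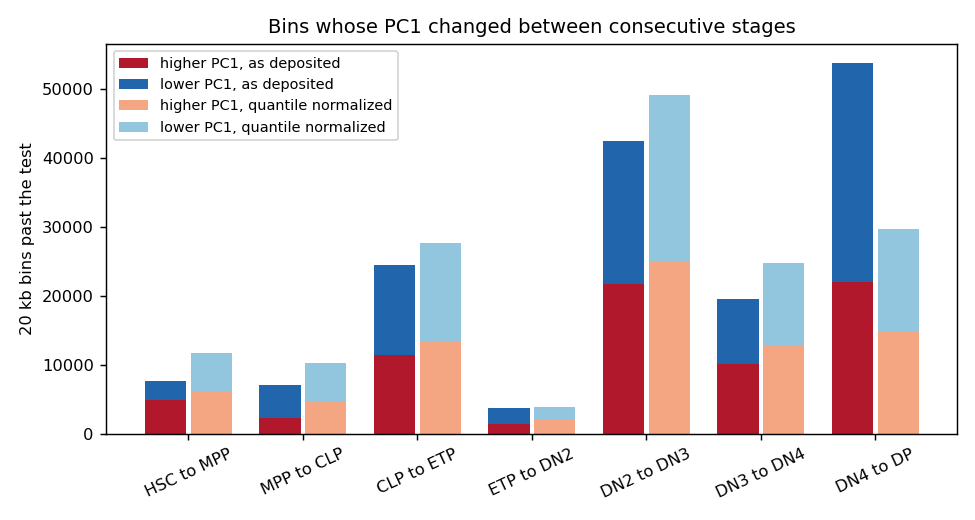
Number of 20 kb bins (y axis) whose PC1 was higher or lower after each step (x axis), as deposited and after quantile normalization between libraries. From DN4 to DP, 31927 bins are lower as deposited and 14915 after quantile normalization.

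DNase-seq asked where chromatin opens or closes along the same stages. The interval on chromosome 12 from 107380001 to 109200000 held more accessible islands from DN2 onward. It held a mean of 3.5 islands in HSC, 5.5 in MPP, 3.5 in CLP, 4.5 in ETP, 24.5 in DN2, 119 in DN3, 113 in DN4 and 102.5 in DP (n = 2 each). Across the genome, 186 regions were present in all 6 libraries of DN3 to DP and absent from all 10 of HSC to DN2, and 50 showed the reverse. The late-only regions with the highest scores lay on chromosome 12 at 111715601 to 111718500, 108361301 to 108365000 and 108966501 to 108969500, on chromosome 11 at 107435801 to 107438300 and on chromosome 2 at 91056701 to 91058400. The early-only regions with the highest scores lay on chromosome 15 at 75686801 to 75689100 and 73261301 to 73266900, on chromosome 6 at 116598901 to 116601100, on chromosome 8 at 123855101 to 123859400 and on chromosome 4 at 153892101 to 153894700. PC1 rose by 89.4 and 111.8 in the bins of the regions of chromosome 12 that start at 108361301 and 108966501 and by 13.6 in that of chromosome 11, and fell by 21.4 and 46.0 in those of chromosomes 6 and 4. The bins of the other 5 regions did not pass, with changes of 2.84 (chromosome 12), 3.38 (chromosome 2), -1.42 and -4.37 (chromosome 15) and -1.76 (chromosome 8; adjusted p from 0.059 to 0.548). DN2 to DN3 brought the most gains of any step, with 2403 regions in both libraries of DN3 and neither of DN2 against 861 the other way. DN4 to DP brought the most losses, 4253 against 670 gains. When every library kept the same number of islands, DN4 to DP lost 2841 and gained 3353 regions, and DN2 to DN3 lost 1693 and gained 1719, so the step with the most gains changed. The remaining steps gained and lost 568 and 330 (HSC to MPP), 630 and 301 (MPP to CLP), 224 and 941 (CLP to ETP), 975 and 314 (ETP to DN2), and 212 and 1637 regions (DN3 to DN4).

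Islands numbered 53685 to 98240 per library at 1:30 and 37508 to 55632 at 1:20, and merged into 134066 regions, of which 15202 were in all 16 libraries. On average, libraries of the same stage shared more islands than those of other stages (mean Jaccard index 0.395 against 0.346). An exact permutation over all 40320 orders of the stages gave p = 2.5e-05, the smallest they can give. The index was highest for DP (0.646), while CLP (0.298), ETP (0.331), MPP (0.333) and DN4 (0.339) lay below the mean of other stages. For 2 of 8 stages, DN3 and DP, the 1:20 library nearest to the 1:30 library was of the same stage. The 1:20 library of DN3, which had the most islands at 1:20, was also nearest to the 1:30 libraries of HSC, MPP, CLP, ETP and DN2. Within the 1:30 libraries the index was 0.605 among early stages, 0.522 among late stages and 0.483 between them, and within the 1:20 libraries 0.497, 0.474 and 0.426. The count of 236 late-only or early-only regions was 376 without DN3 replicate 1, 380 without DN3 replicate 2, 381 without DN2 replicate 1 and 386 without DN4 replicate 2. It was 5745 in the 1:30 and 1770 in the 1:20 libraries alone, and with the same number of islands from every library it was 690 (394 late-only, 296 early-only).

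Contact matrices of HSC, DN2 and cultured DN2 and DN3 cells showed how strongly like compartments met. Within the chromosome 12 interval, contacts over the mean of their distance were 1.57 in HSC and 2.40 in DN2, and 2.26 and 2.76 in cultured DN2 and DN3. Contacts of this interval with bins that were positive at every stage were 0.633 in HSC and 1.15 in DN2, and 1.33 and 1.51 in the cultured cells. Over 119 runs that turned positive, the ratio of contacts with constant A over constant B bins was 0.865 in HSC and 0.957 in DN2, and 1.14 and 1.27 in cultured DN2 and DN3. Over 128 runs that turned negative it was 1.07 and 0.962, and 0.869 and 0.817. Contacts within a compartment exceeded those between compartments by a factor of 1.75 in HSC, 1.88 in DN2, 1.78 in cultured DN2 and 1.78 in cultured DN3. These were single matrices without replicates. Runs were chosen by PC1 of the stages, and constant bins by PC1 of the stage, cultured and naive libraries. PC1 itself comes from Hi-C contacts, so shifts of these contact ratios are in part built in. PC1 of the cultured DN2 library correlated with that of DN2 and DN3 thymocytes at 0.957 and 0.956 across bins, and that of the cultured DN3 library with DN3 and DN4 at 0.961 and 0.961, where bins are not independent replicates.

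Pooled interaction lists held 361088 (MPP) to 735509 (DN3) pairs. As a share of the summed pair numbers of each list, pairs with an end in a late-only accessible region made up 915.7 ppm in HSC, 889.9 in MPP, 952 in CLP, 948 in ETP, 964 in DN2, 1466 in DN3, 1532 in DN4 and 1709.7 in DP. The share also rose at regions open in all 16 libraries, from 106848 ppm in HSC to 127825 in DN3 and 125397 in DP, and pairs at early-only regions were highest in DP, with 266 in HSC, 226 in DN3 and 292 in DP. Pairs within the chromosome 12 interval were at 71.5 ppm in ETP, 97.3 in DN2, 142 in DN3, 173 in DN4 and 206 in DP, in lists without replicates. The share of pairs 0.5 to 2 Mb apart was 4.85% in HSC, 8.20% in MPP, 6.21% in CLP, 4.24% in ETP, 2.39% in DN2, 2.09% in DN3, 1.97% in DN4 and 1.77% in DP.

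Nucleosome positions of DN2 (7098762) and DN3 (6708089), with 1 library each, differed little at the accessible regions. Median occupancy at late-only regions was 14.25 in both stages, at early-only regions 15.25 in DN2 and 17.25 in DN3, and at regions open in all 16 libraries 13.25 and 14.25. In the chromosome 12 interval it was 13.0 in DN2 and 12.75 in DN3. Positions were denser in the A than in the B compartment, with 3.45 against 2.20 per kb in DN2 and 3.33 against 2.00 in DN3.

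RNA-seq of naive CD4 T cells asked which genes differ between Bcl11b knockout and control libraries. Bcl11b fell from an RPKM of 57.6 and 54.9 in the controls to 6.16 and 8.37 in the knockouts (log2 change -2.89 ± 0.14, SE, n = 2 per group, adjusted p = 8.5e-08). The remaining reads cannot be split between undeleted cells and undeleted parts of the transcript. Fcer1g, the Fc receptor gamma chain, went from 8.62 to 317 (5.26 ± 0.18, adjusted p = 2.3e-09) and Cd160, an NK and CD8 receptor, from 2.43 to 65.7 (4.81 ± 0.16, adjusted p = 2.3e-09). Of 16 interferon response genes 14 rose, although the list did not pass with an estimated correlation (adjusted p = 0.0715), with Ifit3 from 14.2 to 90.0 (2.72 ± 0.20) and Ly6a from 147 to 442 (1.64 ± 0.13). Lgals1, which encodes galectin-1, fell from 164 to 54.8 (-1.53 ± 0.11). In all 651 genes rose and 460 fell of 10940 tested, and 90 and 29 of them changed at least 4-fold.

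Among the largest increases were Moxd1, with a ratio of 491.6 (counting interval 87.82 to 19460), Mag with 233.2 (64.19 to 1931), Abhd12b with 44.32 (11.91 to 371.7), Slc35f5 with 43.32 (14.49 to 212.8) and Hemgn with 27.87 (9.212 to 137.9). Bpifa2e was at least 30.2-fold higher, against no reads in the controls, and Tgfb3 rose by 4.88 ± 0.45 and March8 by 4.55 ± 0.43. The largest decreases held the beta globins, which make hemoglobin in red cells: Hbb-b1 was at least 34.1-fold lower, Hbb-b2 at least 33.4-fold lower, and Beta-s had a ratio of 285.2 (97.28 to 1386). Here and in DP thymocytes, genes typical of other cell types were not tested for reads from other cells in a library. Hist1h4m was at least 16.2-fold and Myl10 at least 5.96-fold lower. Gt(ROSA)26Sor changed by -3.79 ± 0.48, the heme enzyme Alas2 by -3.17 ± 0.69, Galnt9 by -3.07 ± 0.37 and Adamts14 by -2.85 ± 0.48.

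By list, 14 of 16 interferon response genes rose and 0 fell in naive cells (16 and 0 adjusted over the list alone; median log2 change 1.36; camera adjusted p = 5.1e-11, and adjusted p = 0.0715 with an estimated correlation). Of 20 NK and innate lymphoid genes 7 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.000966, and adjusted p = 0.201 with an estimated correlation), with the NK receptors Klrb1c and Klrd1 up by 1.80 ± 0.36 and 1.79 ± 0.25. Of 14 B-lineage genes 5 rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 0.0108, and adjusted p = 0.205 with an estimated correlation), with the B-cell surface protein Ms4a1 at 18.5 and 31.5. Of 30 T lineage identity genes 10 fell and 0 rose (12 and 1 adjusted over the list alone; median -0.20; adjusted p = 0.00011, and adjusted p = 0.0740 with an estimated correlation), with the signalling adaptor Lat at -0.69 ± 0.09 and Cd8a at -0.75 ± 0.10. Of 5 erythroid genes 3 fell (4 adjusted over the list alone; median -3.17, and -3.17 with genes at their bounds; adjusted p = 0.000183, and adjusted p = 0.119 with an estimated correlation). Of 8 stem and progenitor genes 1 rose, Ly6a, which the interferon list also holds (2 adjusted over the list alone; adjusted p = 0.0487, and adjusted p = 0.201 with an estimated correlation). The stroma list passed with 0 of 4 members past the threshold (2 adjusted over the list alone; median 1.06, and 0.77 at bounds; adjusted p = 0.0195, and adjusted p = 0.177 with an estimated correlation).

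The other lists did not pass in naive cells. Naive and recirculation genes had 2 of 15 up, Il7r (1.25 ± 0.11) and Igfbp4 (0.71 ± 0.11), and 2 down (5 and 3 adjusted over the list alone; adjusted p = 0.691). Activated and memory T genes had 3 up and 3 down of 21 (3 and 4 over the list alone; adjusted p = 0.857), among them Il2rb at 1.48 ± 0.11. CD8 lineage genes had 3 up and 3 down of 10 (4 and 4; adjusted p = 0.691), with Itgae at -1.47 ± 0.38. Regulatory T genes had 2 up and 1 down of 11 (3 and 1; adjusted p = 0.712), with Nrp1 at 2.41 ± 0.19. Myeloid genes had 3 up and 1 down of 9 (3 and 1; adjusted p = 0.691), Notch genes 2 up of 10, Hes1 and Dtx1 (3; adjusted p = 0.242), and stress genes 2 up and 1 down of 14 (4 and 1; adjusted p = 0.352). Positive selection genes had 2 up and 3 down of 21 (3 and 4; adjusted p = 0.843), genome architecture genes 1 up, Lmna, and 2 down of 21 (1 and 2; adjusted p = 0.612), cell cycle genes 1 down of 22, Cdc20 (0; adjusted p = 0.745), gamma delta genes 1 down of 4, Sox4 (1; adjusted p = 0.352), and helper regulators 0 of 6 (0; adjusted p = 0.994). The median and the test differed in sign for the activated, helper, positive selection and cell cycle lists.

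Naive counts depended on single libraries: 568 genes passed without control replicate 2, 630 without knockout replicate 1 and 430 without knockout replicate 2. With limma on log2(RPKM + 1) 527 rose and 578 fell, and with a pseudocount of 0.1 391 rose and 470 fell.

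The same question was asked in DP thymocytes. All 22 cell cycle genes fell, although the list did not pass with an estimated correlation (adjusted p = 0.0566). Top2a, the topoisomerase of dividing cells, fell from an RPKM of 70.5 to 0.740 (log2 change -6.43 ± 0.14, SE, n = 2 per group, adjusted p = 2.6e-11), the mitotic kinase gene Nek2 from 33.3 to 0.236 (-6.99 ± 0.26) and Ube2c from 190 to 2.80 (-5.94 ± 0.20). S1pr1, the receptor that guides exit from the thymus, rose from 11.1 to 73.8 (2.87 ± 0.10, adjusted p = 4.5e-10), its regulator Klf2 from 5.20 to 38.9 (3.04 ± 0.14) and Zbtb7b, the CD4 lineage factor, from 0.510 to 5.94 (3.67 ± 0.22). Cd160 rose from 0.571 to 18.5 (5.15 ± 0.20), as it had in naive cells. Bcl11b fell from 108 and 124 to 46.2 and 39.1 (-1.31 ± 0.13, adjusted p = 8.4e-06), less than in naive cells (naive minus DP log2 effect -1.59 ± 0.19, adjusted p = 7.3e-05), and the same limit holds for its remaining reads. In all 1945 genes rose and 1264 fell, 342 and 262 of them at least 4-fold.

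**Figure D3:**
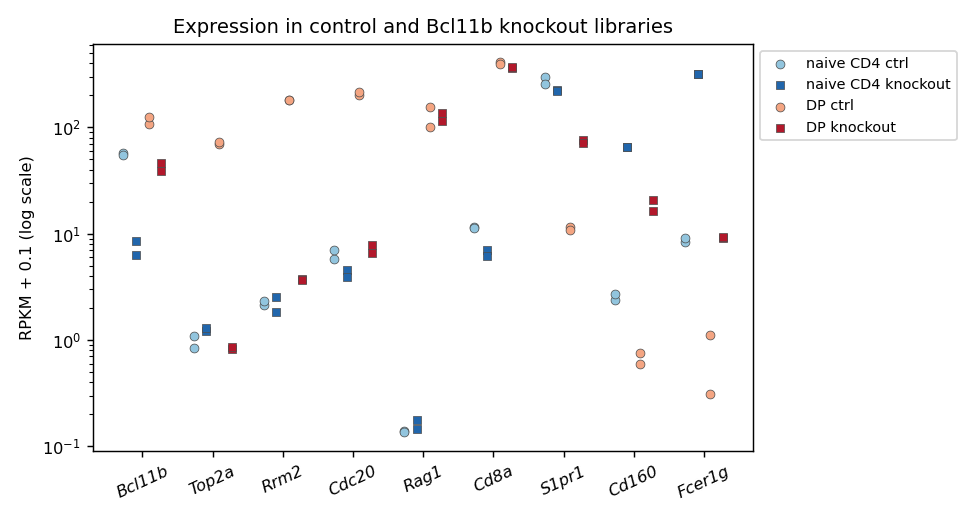
RPKM + 0.1 (y axis, log scale) of 9 genes per library (points) in control and Bcl11b knockout libraries of naive CD4 T cells and DP thymocytes, 2 per group. Mean Top2a is 70.5 in DP controls and 0.740 in DP knockouts.

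The largest DP increases against no reads in the controls were those of Col1a2 (at least 75.3-fold higher), Wisp2 (at least 44.9-fold higher), Sccpdh (at least 35.2-fold higher), Rhod (at least 33.9-fold higher), Prss30 (at least 17.5-fold higher), Slpi (at least 12.6-fold higher) and S100a1 (at least 8.08-fold higher). Lyz2 rose by 5.76 ± 0.58 and Lyl1 by 5.43 ± 0.55, and Otos had a ratio of 48.48 (8.312 to 1953). Among the largest decreases, Rad54b was at least 90.75-fold lower, E2f7 had a ratio of 644.5 (115.3 to 25500) and Clspn 292.9 (99.88 to 1423). Cdc6 fell by 6.97 ± 0.42, Spag5 by 6.95 ± 0.36, Kif4 by 6.94 ± 0.27, E2f8 by 6.74 ± 0.51, Exo1 by 6.68 ± 0.53 and Melk by 6.61 ± 0.53 on the log2 scale.

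By list, the 22 cell cycle genes had a median log2 change of -4.91 in DP (22 down adjusted over the list alone; camera adjusted p = 4.5e-27, and adjusted p = 0.0566 with an estimated correlation). Of 20 NK and innate lymphoid genes 15 rose and 0 fell (15 and 0 adjusted over the list alone; adjusted p = 8.7e-08, and adjusted p = 0.102 with an estimated correlation). Of 15 naive and recirculation genes 11 rose (12 adjusted over the list alone; adjusted p = 3.8e-06, and adjusted p = 0.0715 with an estimated correlation), with Igfbp4 from 8.15 to 61.2 and Il7r, the interleukin 7 receptor, up by 2.85 ± 0.14. Of 21 positive selection genes 15 rose and 1 fell (16 and 2 adjusted over the list alone; adjusted p = 0.000138, and adjusted p = 0.0740 with an estimated correlation), with the survival factor Bcl2 at 2.32 ± 0.13 and Gimap4 at 2.24 ± 0.14. Of 16 interferon response genes 11 rose (12 adjusted over the list alone; adjusted p = 0.000264, and adjusted p = 0.119 with an estimated correlation), with Oasl2 at a ratio of 19.88 (5.163 to 169.7). Of 21 activated and memory T genes 11 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 0.000681, and adjusted p = 0.177 with an estimated correlation), with Cxcr3 at 2.54 ± 0.28. Of 10 CD8 lineage genes 6 rose (6 adjusted over the list alone; adjusted p = 0.00435, and adjusted p = 0.119 with an estimated correlation), with Runx3 at 2.07 ± 0.21. Of 11 regulatory T genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.0487, and adjusted p = 0.201 with an estimated correlation), with Gpr83 at 2.72 ± 0.19. Of 10 Notch pathway genes 4 fell and 1, Hes1, rose (6 and 1 adjusted over the list alone; median -0.65; adjusted p = 0.0275, and adjusted p = 0.203 with an estimated correlation), with Ptcra from 184 to 41.4 and Notch3 at -1.71 ± 0.24.

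Lists that did not pass in DP held called genes too. T lineage identity genes had 5 up and 3 down of 30 (5 and 3 adjusted over the list alone; adjusted p = 0.785), with the adhesion receptor Cd2 from 31.5 to 131. Genome architecture genes had 2 up and 7 down of 21 (2 and 7; adjusted p = 0.141), with the lamin gene Lmnb1 from 126 to 43.1 and the cohesin gene Rad21 from 15.6 to 6.95. Stress genes had 6 up of 14 (7; adjusted p = 0.079), with Ier2 at 1.83 ± 0.11, and thymic stroma genes 3 up of 4 (3 and 1; adjusted p = 0.0874), with the collagen gene Col1a1 at 3.16 ± 0.37. Helper regulators had 2 up of 6, Zbtb7b and Tbx21 (2; adjusted p = 0.188), stem genes 4 up and 1 down of 8 (4 and 2; adjusted p = 0.464), myeloid genes 3 up and 2 down of 9 (3 and 2; adjusted p = 0.785), B-lineage genes 1 up of 14, Ebf1 (0; adjusted p = 0.691), erythroid genes 1 up of 5, Gata1 (1; adjusted p = 1), and gamma delta genes 0 of 4 (0; adjusted p = 0.691). The split of called genes shifted to 1213 up and 1927 down with limma on log2(RPKM + 1), and to 1214 up and 1772 down with a pseudocount of 0.1. The median log2 change of all genes then went from 0.07 to -0.05 and -0.06.

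Testing the difference between the cell types, 786 genes had a more positive effect in naive CD4 T cells and 1162 in DP thymocytes. The positive side held the cell cycle genes Top2a (naive minus DP log2 effect 6.89 ± 0.22, adjusted p = 1.7e-09), Rrm2 (5.50 ± 0.23), Tacc3 (4.29 ± 0.21) and Cdc20 (4.17 ± 0.21), and Anxa2 (4.59 ± 0.15), which went from 11.6 to 88.8 in naive cells and from 379 to 112 in DP. Top2a, Rrm2 and Cdc20 stood at 0.873, 2.13 and 6.26 in naive controls, against 70.5, 181 and 207 in DP controls. They thus had far less expression to lose in naive cells. The negative side held the trafficking genes S1pr1 (-3.14 ± 0.13) and Itgb7 (-3.06 ± 0.13), and Ccnd2 (-2.72 ± 0.12), Fam101b (-3.85 ± 0.19) and Gimap3 (-2.40 ± 0.12). With limma on log2(RPKM + 1) the split was 1081 and 859. Sex could not be told apart from cell type here: Eif2s3y, a Y-linked gene, stood at 22.8 to 26.5 in the naive libraries and at most 0.0842 in the DP libraries, and Xist stood at 19.7 to 22.9 in the latter. Genes that rose in naive cells were more often among those that rose in DP, 343 against 115.7 if independent (Fisher's exact test, odds ratio 6.04, p = 9.7e-98), and 89 fell in both against 53.1 (1.90, p = 6.9e-07). By the same exact test, opposite directions were shared by 46 genes up in naive and down in DP against 75.2 (0.566, p = 0.00011) and 106 the other way against 81.8 (1.41, p = 0.00336), where genes are not independent replicates.

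Hi-C of naive CD4 T cells asked whether compartments change in the Bcl11b knockout. On chromosome 7, PC1 of the bin from 113360001 to 113380000 rose from 13.5 to 54.3 (change 40.78, n = 2 per group, limma adjusted p = 0.0015), and on chromosome 10 that from 24000001 to 24020000 rose from 24.8 to 65.0. The longest switched interval, 9260001 to 9520000 of chromosome 14, turned from -20.7 to 10.4. The largest loss, 138140001 to 138160000 of chromosome 7, was from 56.1 to 25.8 (change -30.25, adjusted p = 0.00448). In all 3465 bins (2.76%) changed, 2631 up and 834 down, and 282 turned positive and 57 negative, while 23086 of 125426 bins had an unadjusted p under 0.05. Quantile normalization gave 2332 up and 1794 down, and 1551 bins changed without control replicate 1, 1872 without control replicate 2, 2256 without knockout replicate 1 and 4475 without knockout replicate 2.

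DNase-seq of naive CD4 T cells asked which regions close or open without Bcl11b. Of 50036 regions 1483 were present in all 3 controls and no knockout, and 1176 in all 3 knockouts and no control, while 28581 were in all 6 libraries. The control-only regions with the highest scores lay on chromosome 4 at 133275501 to 133276200, chromosome 10 at 120062401 to 120063100, chromosome 15 at 78945501 to 78946100, chromosome 14 at 20831601 to 20832500 and chromosome 7 at 123584901 to 123585200. The knockout-only regions with the highest scores lay on chromosome 16 at 5029801 to 5030500, chromosome 17 at 85280101 to 85280900, chromosome 2 at 166435601 to 166436400 and 32591701 to 32592700, and chromosome 9 at 96551001 to 96551800. PC1 fell in the knockout by 15.1 in the bin of the control-only region of chromosome 10 (adjusted p = 0.00809) and by 11.4 in that of the knockout-only region of chromosome 2 at 166435601 (adjusted p = 0.0190), and the other 8 bins did not pass. Libraries of the same genotype shared more islands (mean Jaccard index 0.658 among controls, 0.658 among knockouts) than libraries of different genotype (0.614), with 39117 to 46059 islands per library. With 3 libraries per group no split can reach a share under 0.1. The direction depended on the number of islands: with the same number from every library 981 regions were control-only and 1498 knockout-only. Without control replicate 3 the total of 2659 became 4075.

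BCL11B ChIP-seq asked whether these regions are bound by the protein in naive CD4 T cells. Regions that stayed open were bound most often: 61.9% of regions in all 6 DNase libraries overlapped BCL11B islands of both ChIP libraries, against 16.05% of control-only and 26.6% of knockout-only regions. The odds ratio was 0.117 for control-only regions (95% interval 0.102 to 0.135, Fisher's exact test, p = 4.9e-276) and 0.223 for knockout-only regions (0.195 to 0.255, p = 7.5e-128). Control-only and knockout-only regions had median lengths of 500 and 600 bp, against 900 bp for shared regions. Against shared regions matched on length and score, by the same exact test, the odds ratio was 0.572 for control-only regions (0.472 to 0.693, p = 4.8e-09), and it was 0.922 for knockout-only regions (0.766 to 1.11, p = 0.406), which did not pass the threshold. The matched sets held 1282 regions for 1483 control-only regions and 1176 for 1176 knockout-only regions. The match of control-only regions was therefore incomplete. Without matching, control-only regions were bound less often than knockout-only regions (odds ratio 0.527, 0.434 to 0.640, Fisher's exact test, p = 3.4e-11), and their scores were lower, with median percentiles of 20.05 and 30.84. The 2 ChIP libraries held 16395 and 18984 islands, of which 93.7% and 81.2% overlapped those of the other.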

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

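The tests of explanations in this part were chosen after the results were seen, while the test of the difference between cell types was planned. The knockout effect differed between naive CD4 T cells and DP thymocytes for 1948 genes. Among those named, the naive minus DP log2 difference was 6.89 for Top2a, 5.50 for Rrm2, 4.59 for Anxa2, 4.29 for Tacc3 and 4.17 for Cdc20. Top2a, Rrm2 and Cdc20 were already low in naive controls, at 0.873, 2.13 and 6.26 RPKM. The difference was -3.85 for Fam101b, -3.14 for S1pr1, -3.06 for Itgb7, -2.72 for Ccnd2 and -2.40 for Gimap3. Naive and DP libraries also differ in the expression of Xist and Y-linked genes, so sex stays open as a part of this difference.

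The fall of all 22 cell cycle genes in the DP knockout libraries, which kept Bcl11b at 46.2 and 39.1 RPKM, is a part of this difference. Non-cycling cells of another type would have to replace most of the knockout sample, since the cell cycle genes kept a median of 0.0301 of their control RPKM, yet 9 T lineage identity genes with DP-high expression kept a median of 0.907 (0.988 for Rag1 and 0.907 for Cd8a, with Ptcra lowest at 0.224). Scaling between libraries also cannot account for it, because the median log2 change of the list was at most -3.76 over 5 scalings. Control libraries with unusually many cycling cells stay open. The DP library of the stage series minus the DP controls gave a median difference of log2(RPKM + 1) of -1.11 over the list. The same library minus the knockouts gave 2.09, where the added 1 shrinks differences at low RPKM. A single outside library cannot say which level is usual. A lower share of dividing DP cells in the knockout, whether through the gene or through the sort, may account for what remains, and no test here separates these.

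Hi-C libraries were compared within the 4 stages with at least 4 libraries, for 12 measures and 48 group tests, and 5 values from 4 libraries stood apart from the rest of their stage, where chance marks about 1 in 20 groups. DN3 replicate 3 had an SD of PC1 over bins of 69.3, against 71.5 to 72.6 in the other DN3 libraries. The same library had a mean PC1 of 62.9 on chromosome 12 from 107380001 to 109200000, against 69.2 to 72.4. DP replicate 5 had a mean of -11.9 on chromosome 17 from 43160001 to 44140000, against -5.61 to -3.66. DN3 replicate 6 had a mean of 2.44 on chromosome X from 133880001 to 134760000, against -14.8 to -11.8. ETP replicate 4 had a mean of 6.12 on chromosome 2 from 8620001 to 9320000, against -9.74 to -7.28.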

How the results depend on the processing

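The alternatives added after the data were seen were limma on log2(RPKM + 1), DESeq2 and its size factors, the crossed replicate block, turning the sign of chromosomes 2 and X in DN2 replicate 2, the regions matched on length and score, leaving out a ChIP library, and the distance corrections of contact maps. For the 22 results of comparisons, 381 of 425 alternatives stayed within 1.5 times the count or kept the side of the threshold. For 184 named genes and regions, 3033 of 3217 did, 113 lost the call and 71 gained it, and no called gene or region changed sign. Of the 381, 277 left out a library, and many of these libraries were of stages outside the step compared. Such counts could hardly move, so the share overstates how stable the results are. Among alternatives of comparisons that left out no library, 104 stayed, 26 moved and 1 lost the call. The alternative that relates PC1 to the expression of genes was not run, because no mm9 gene positions were used here. For stage RNA the absence of replicates, and for knockouts 2 libraries per group, set the limits; with 1 library left in a group its spread was taken from the other groups. Where no cause is given, the cause was not tested.

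The larger side, up or down, changed in 23 of 403 alternatives of 15 counts, and 1 was even (188 late-only and 188 early-only regions without DN3 replicate 1). With limma it became down in naive cells (527 up, 578 down; 391 and 470 with a pseudocount of 0.1) and in DP (1213 and 1927; 1214 and 1772; 1150 and 1746 without trend). The interaction turned to more positive in naive cells (1081 and 859; 904 and 850; 1019 and 776). The same number of islands gave 1498 knockout-only and 981 control-only regions. With a change of at least 0.5 SD, 1945 bins rose and 35 fell from DN4 to DP, 116 and 691 from DN3 to DN4, and 177 and 168 from ETP to DN2. Quantile normalization gave 2125 and 1711 from ETP to DN2, and 2237 and 2105 with signs turned. From DN2 to DN3 49.75% rose without DN2 replicate 3, and from DN3 to DN4 49.93% with the replicate block. Between early and late stages 50.13% to 51.79% rose under 7 alternatives, against 49.38%.

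Requiring a change of at least 0.5 SD left fewer PC1 bins by construction: 1299 from HSC to MPP, 1024 from MPP to CLP, 3163 from CLP to ETP, 345 from ETP to DN2, 12345 from DN2 to DN3, 807 from DN3 to DN4, 1980 from DN4 to DP, 9694 between early and late stages and 9 in naive cells. Quantile normalization gave 11708 from HSC to MPP and 29760 from DN4 to DP. With the signs of DN2 replicate 2 turned as well it gave 14032 from HSC to MPP and 11782 from MPP to CLP. Library series as a batch term gave 5583 from ETP to DN2. Leaving out libraries gave 2138 to 8309 bins from MPP to CLP, 1846 to 20277 from ETP to DN2, 27037 to 45807 from DN2 to DN3 and 1551 to 4475 in naive cells. Counts were lowest without MPP replicate 1 (MPP to CLP), ETP replicate 2 (ETP to DN2), DN2 replicate 2 (DN2 to DN3) and control replicate 1 (naive cells). They were highest without MPP replicate 2 (MPP to CLP), DN2 replicate 3 (ETP to DN2 and DN2 to DN3) and knockout replicate 2 (naive cells).

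Late-only or early-only accessible regions numbered 690 with the same number of islands from every library, 134 with the islands above the median score, 63 when an island had to cover 50% of the region, and 238 to 386 without 1 library, highest without DN4 replicate 2. Control-only or knockout-only regions numbered 3216 to 4075 without 1 library, highest without control replicate 3. Fewer libraries that must concur raise such counts by construction. BCL11B binding of knockout-only regions had an odds ratio of 0.922 (p = 0.406) against matched regions, over a range of Fisher's exact p from 4.6e-133 to 0.406. Stage RNA gave 617 genes with a pseudocount of 0.1 and 82 at 4-fold. With an estimated correlation 0 of the 16 gene list calls passed.

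The replicate numbers were also used as a block. It gave 651 genes in naive cells, and leaving out libraries gave 430 to 1320, lowest without knockout replicate 2. Deviations of control 1 and knockout 1 from their group means correlated at -0.0802 in naive cells and -0.133 in DP across genes. These values gave no sign of pairing by number, but 1 value per cell type cannot exclude it. In DNase-seq the 1:30 libraries alone gave 5745 and the 1:20 libraries alone 1770 late-only or early-only regions. Naive libraries numbered 1, 2 and 3 alone gave 12142, 12827 and 11182 control-only or knockout-only regions. With the DP numbers crossed, 873 genes changed in naive cells and 3004 in DP, and 1729 differed between them.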

Other observations

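The tests of explanations and hypotheses in this part were chosen after the results were seen, except the regroupings of the samples for stage expression, stage DNase-seq and naive DNase-seq. Lineage genes outside the T programme differed in the stage library where they were highest. With 1 library per stage, timing cannot be told apart from reads of other cells in a library. S100a8, an alarmin of neutrophils, stood at an RPKM of 1977 in HSC, 651 in MPP, 311 in CLP and 3.10 in ETP. The B-lineage genes Blnk and Igll1 were highest in CLP, at 149 and 128. Fcer1g, which rose in the knockouts of both cell types, stood at 250.0 in CLP, 77.5 in DN2 and 2.74 in DN3. Gzma, a cytotoxic granule protease, peaked in DN4 at 866, against 1.09 in ETP. Myc stood at 321 in DN4 and 12.5 in DP. Some T-cell transcripts were higher in the HSC than in the MPP library, such as Cd3g at 20.7 against 1.84 and Ptcra at 5.01 against 0.399. Beta globin reads, with Hbb-b2 at 60.2 in HSC and 48.4 in ETP, were also highest in DN2.

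In DN2 replicate 2, PC1 ran against all other libraries on chromosomes 2 and X. A sign set separately for every chromosome and library may account for this, since the weaker of both correlations with the median library was -0.986, nearly a mirror image. The nearest stage library was of DN2 on each of its 18 other chromosomes (without Y). Both other DN2 libraries were closer to it over these (r of at least 0.9937 across bins) than any library of another stage (at most 0.9918). This argues against a library of another stage but does not exclude it. For DN2 replicate 3 the nearest library was of DN2 on 3 of 18 chromosomes. Over all, replicate 3 was nearest to ETP replicate 4 (r = 0.9947, against 0.9928 at the lowest within DN2). For MPP replicate 2 the nearest was of MPP on 5 of 18, and over all it was CLP replicate 3 (r = 0.9912, against 0.9897 for MPP replicate 1). Both carry the tissue label thymus and share a library series, so label and series cannot be told apart. Without MPP replicate 2, 5284 bins changed from HSC to MPP and 8309 from MPP to CLP. Cell populations outside the stages were not tested.

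From DN4 to DP, 94.45% of the bins that switched sign turned positive (3865 against 227). With library series as a batch term the share was 94.26%. The signs there came from stage means without that adjustment, so the share could hardly move. Library series as the source was therefore not excluded. The share was 52.05% after quantile normalization, but this gives all libraries the same share of positive bins and so decides nothing. As deposited, 50.2% of bins were positive in DP and 46.0% to 48.9% in the earlier stages. An offset or spread of PC1 that differs between libraries and a real shift of chromatin towards the A compartment in DP cannot be told apart here, because both change that share.

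A hypothesis was that accessibility and compartments change at the same places. Late-only accessible regions lay where PC1 rose, with a mean late minus early change of 16.3 (n = 186; circular shifts of the regions, permutation p = 0.001, the smallest they can give), and 11.3 without those of the chromosome 12 interval. Regions open in all 16 libraries also lay where PC1 rose (mean 6.17, n = 15132, permutation p = 0.001, the smallest possible), so the rise was not tied to a gain of accessibility alone. Early-only regions lay where PC1 fell (mean -7.55, n = 50, permutation p = 0.012). In naive CD4 T cells, control-only regions lay where PC1 fell in the knockout (mean -1.22, n = 1479, permutation p = 0.001, the smallest possible), but regions open in all 6 libraries had a mean of -0.54 as well. For knockout-only regions the mean change was 0.128 (permutation p = 0.48), which settles nothing. Late-only regions were not tested against regions whose presence did not change, and a causal order was not tested.

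Other groupings of the same samples were tried for every comparison with at least 3 samples per group. Expression across the stages gave 328 genes for the real grouping and at most 90 for the others, and 1 of 56 groupings gave as many as the real grouping. Stage DNase-seq gave 236 regions and at most 11 otherwise (1 of 56). PC1 gave 24471 bins from CLP to ETP and at most 17489 otherwise (1 of 35), 3693 from ETP to DN2 and at most 1928 (1 of 35), 42481 from DN2 to DN3 and at most 20176 (1 of 84), 19512 from DN3 to DN4 and at most 3536 (1 of 100), 53894 from DN4 to DP and at most 36739 (1 of 100), and 75835 between early and late stages and at most 7906 (1 of 100). The real grouping is the 1 counted in each case. The stages follow an order and are not exchangeable, so for expression and stage DNase-seq chance was not excluded. Between early and late stages, PC1 regroupings exchanged single libraries. Any difference between stages could make the real grouping largest, and whole stages were not regrouped. ETP to DN2 and DN2 to DN3 included the DN2 library with reversed signs, and their counts depended on single libraries. Chance was not excluded for ETP to DN2, DN2 to DN3 or early against late stages. For the other PC1 steps regrouped, chance exchange of libraries is an unlikely source. The regroupings of PC1 exchanged libraries without regard to library series, although deviations from the stage mean were more alike within a series (median r = 0.215 across bins) than between series (-0.0594). With series as a batch term the real groupings gave 28545, 5583, 47047, 22409, 56319 and 76734 bins in the same order. For naive DNase-seq, with 2659 regions and at most 275 otherwise, the 10 groupings (1 as large, the real one) are too few for a share under 0.05.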
